A study of Mus musculus with 12 samples.

How the data were processed

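Lungs of Balb/c mice were snap frozen, and total RNA was isolated with a column kit per the submitters' protocol. Labelling started from 300 ng of RNA with the WT Plus reagent kit and biotin, per the labels, and Affymetrix mouse Gene 1.0 ST arrays were hybridised. The eosinophilic model used 3 intraperitoneal injections of HDM extract with 0.75 DU of each allergen and 1.5 mg of aluminium hydroxide, then intranasal challenge on days 26 to 28. The mixed and neutrophilic models used 4 weekly intranasal applications with 0.75 or 7.5 DU of each allergen. DU stands for development units of the extract.

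The deposited values are log2 intensities, one per probe set, that the authors made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA corrects background, normalizes quantiles and summarises probes, and its versions are not given in the sources used here. The base was taken as log2 from the range of the values. No further normalization was applied in the planned fit, and no detection calls were used.

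The table held 34760 probe sets on 12 arrays, without missing values. In the annotation supplied with the platform 22961 probe sets were listed with at least 1 gene, 21640 of them with a single gene symbol and 1321 with several, and 11799 were not listed. Entrez IDs of 21553 of the single-gene probe sets were matched in a RefSeq gene table of GRCm38.p6, and no symbol changed. For each gene the probe set with the highest mean over all 12 arrays stood for it, which left 19937 genes, of which 954 had more than 1 probe set. Probe sets without a single gene were tested apart, over all probe sets.

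Tests ran in R 4.3.3 with limma 3.58.1. A linear model with a mean for each of the 4 groups was fitted to log2 values of all 12 arrays (lmFit), with contrasts between groups and moderated variances (eBayes, no trend). P values were adjusted by the Benjamini-Hochberg method over the 19937 genes within each comparison, two-sided, and adjusted p under 0.05 was the threshold. The count with at least a 2-fold change was taken beside it. No covariate was used, since the labels give no batch, slide or scan date. A moderated F test asked for any difference among the 4 groups. All these choices, the gene lists, the rule for naming genes and the first set of alternative settings were written down before the data were examined.

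Gene lists were fixed from general knowledge for the topics in the study title (tight junctions, adherens junctions, mucins, goblet cells, inflammasome), for immune axes, for cell types of lung and for tissues that dissection can bring along. Each of 46 lists was tested with camera (preset inter-gene correlation 0.01), with camera using an estimated correlation and with fry, and p values were adjusted over the lists within a comparison. Members past the threshold were counted over all genes tested and again with p adjusted over the list alone. A score for each array was the mean of the members minus their control mean. Mpp5 stands for Pals1, as named in the annotation.

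Genes were named in the report by a fixed rule. Per comparison these were the 6 largest rises and 6 largest falls among genes past the threshold whose 3 values in one group all lay beyond those of the other, without predicted, clone, micro RNA or sno RNA names. Up to 4 members of each list by smallest p could be added, and any member of the study topic, eosinophil, neutrophil, type 2 and IL-17 lists whatever its p. A gene named for one comparison could be given in the others.

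Alternatives planned beforehand were filters on dim genes (log2 of 5 or more on at least 3 arrays, or above the array median on at least 3), centring each array on its median, quantile normalization, eBayes with trend and robust settings, array weights, fits of only the 2 groups compared, the mean of all probe sets of a gene, all probe sets, and leaving out in turn each array of the groups compared. The filters kept 13370 and 12749 genes. Some settings were added after the ranges of the arrays had been seen. These left out the array of eosinophilic mouse 7 in every comparison, or those of eosinophilic mice 7 and 9 and neutrophilic mouse 23. Another took the SD of each array as a covariate. Array weights were estimated by REML, which did not converge and gave a weight of 85.4 to eosinophilic mouse 9, so that fit carries little information.

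Sharing of calls between comparisons was set against n1 x n2 / N, and correlations of log2 changes against 50 simulated data sets without group effects that kept the spread of each gene and each array and shared the control arrays. The noise in these data sets was independent between genes. Counts were also set against other splits of the same arrays, all 10 for a pair of groups and 100 drawn for the 4 groups. For lists, 10000 random lists matched in 50 bins of mean expression gave the share with a median as low.

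The fit was tried on simulated data with the spread of the real arrays and 50 genes changed at each size in neutrophilic against control mice. It recovered 4% of genes changed by log2 1, 60% at log2 2, 94% at log2 3 and 96% at log2 4, with 2 false calls among 129. Without mouse 7 these were 26%, 88%, 98% and 100%, with 3 false calls among 159. A shifted list was found in each setting and no other list was called. The simulated noise was independent between genes, while members of some lists moved together on these arrays (estimated correlation 0.913 for blood endothelium). These simulations therefore do not show how camera or the gene counts behave under such correlation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.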

Results

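Gene expression was measured in whole lung of 12 Balb/c mice on Affymetrix mouse Gene 1.0 ST arrays, 1 array for each mouse. Per the labels the mice formed 4 groups of 3. Control mice received PBS into the nose. Eosinophilic mice received 3 intraperitoneal injections of house dust mite (HDM) extract on alum, then intranasal challenge with the low dose (0.75 DU each of Der f and Der p). Mixed mice received that low dose by the intranasal route alone, in 4 weekly applications, and neutrophilic mice received 7.5 DU of each allergen on the weekly intranasal schedule. The number of arrays limits the precision of every estimate. Each limma p value below measures spread between mice, pooled over all groups in the fit. A wide spread in 1 group therefore also widens the SE of comparisons without that group. Camera p values instead compare list members with other genes, by default at a preset correlation of 0.01, and do not measure spread between mice.

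The array of eosinophilic mouse 7 stood apart from the other 11. Its values correlated at 0.356 with the median of the other arrays, and its SD was 0.996 log2. The arrays of eosinophilic mouse 9 and neutrophilic mouse 23 also had low SDs (1.52 and 1.51), with correlations of 0.864 and 0.868. Low range below means such a low SD, not narrow extremes. The lowest and highest values were 2.45 and 14.93 on mouse 7, 2.34 and 14.89 on mouse 9 and 2.355 and 14.9 on mouse 23. On control 1 they were 2.274 and 14.61. The remaining 9 arrays had SDs of 1.77 to 2.04 and correlations of 0.956 to 0.980. Along the first principal component, which carried 59.3% of the variance, mouse 7 lay at 197. The second component carried 14.3% and held the groups in the order control (-53.5 to -44.4), eosinophilic (-22.4 to 5.03), mixed (17.9 to 18.1) and neutrophilic (30.6 to 41.4). All 12 arrays stayed in the planned fit, and values without mouse 7 are given beside it for the counts and for some genes and lists. Leaving out each array of the groups compared in turn was planned. Singling out mouse 7, and leaving it out of the other comparisons, was chosen after these data were seen.

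**Figure D1:**
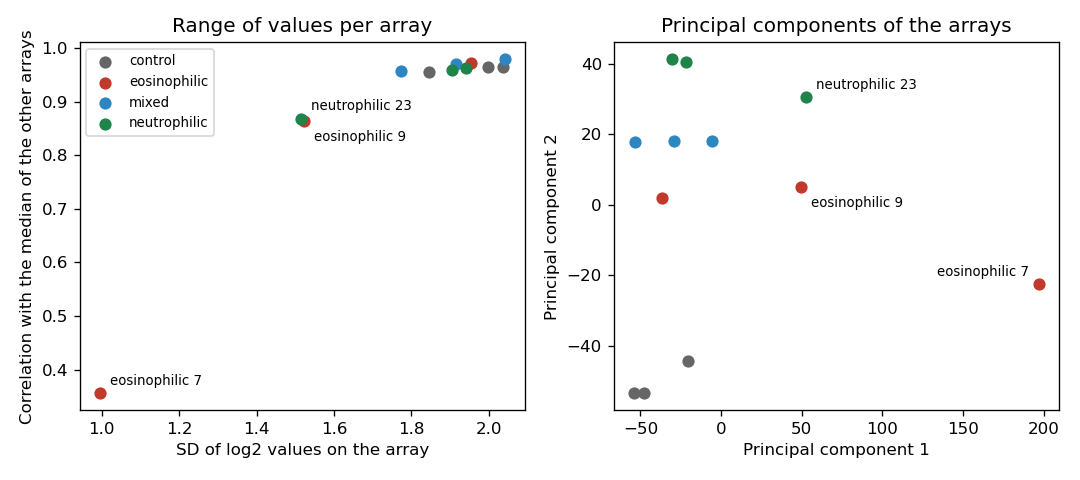
Range of values and principal components of the 12 arrays. The array of eosinophilic mouse 7 had an SD of 0.996 log2 and a correlation of 0.356 with the median of the others.

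The comparison of eosinophilic with control mice asked which lung transcripts changed after intraperitoneal sensitisation and challenge. The largest rise was in Rnase2a, which encodes an eosinophil-associated ribonuclease (log2 5.47, SE 0.96, adjusted p = 0.0462, n = 3 and 3). The chemokine gene Ccl8 rose (log2 4.72, SE 0.89, adjusted p = 0.0462), as did the acute-phase gene Saa3 (log2 4.40, SE 0.54, adjusted p = 0.0242). Arg1, an arginase of alternatively activated macrophages, rose 15-fold (log2 3.90, SE 0.65, adjusted p = 0.0462). The chitinase-like genes Chil3 (log2 3.20, adjusted p = 0.0479) and Chil4 (log2 2.62, adjusted p = 0.0462) rose too, together with the macrophage lectin gene Clec10a (log2 2.13, adjusted p = 0.0347). The proliferation marker Mki67 rose (log2 2.06, adjusted p = 0.0462), and of the neutrophil chemoattractants only Cxcl3 did (log2 1.63, adjusted p = 0.0479).

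Losses in eosinophilic lung were led by Cpm, a membrane carboxypeptidase gene (log2 -3.53, SE 0.67, adjusted p = 0.0462), the incretin receptor gene Glp1r (log2 -3.37, SE 0.53, adjusted p = 0.0373) and the integrin gene Itga8 of pericytes and fibroblasts (log2 -3.30, adjusted p = 0.0462). Lurap1l (log2 -3.19, adjusted p = 0.0462), the antioxidant esterase gene Pon1 (log2 -3.06, adjusted p = 0.00305) and the endothelial apelin receptor gene Aplnr (log2 -3.04, adjusted p = 0.0462) followed. Akap5 of alveolar type 1 cells (log2 -2.81, adjusted p = 0.0462), the club cell secretory gene Scgb3a2 (log2 -2.06, adjusted p = 0.0347), the ciliary gene Sntn (log2 -1.66, adjusted p = 0.0462) and the adherens junction gene Nectin3 (log2 -1.97, adjusted p = 0.0353) also fell. Abundant genes fell in general: over all genes the log2 change had a slope of -0.405 on the control mean, and -0.192 without mouse 7. Without mouse 7 Cpm measured log2 -2.80, Glp1r -2.68, Itga8 -2.42, Lurap1l -2.76 and Aplnr -2.31, while Pon1 stayed at -3.08.

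Genes of the study topics were mostly short of the threshold in eosinophilic mice with all 12 arrays. Clca1, a regulator of mucus in goblet cells, measured log2 4.61 (adjusted p = 0.0547), and the anion exchanger gene Slc26a4 3.22 (0.0957). The gel-forming mucins Muc5ac (log2 1.17, adjusted p = 0.109) and Muc5b (log2 0.87, adjusted p = 0.398) did not pass. Without mouse 7 the limma fit gave log2 6.17, adjusted p = 9.28e-07 for Clca1, log2 4.73, adjusted p = 6.3e-06 for Slc26a4, log2 1.55, adjusted p = 0.031 for Muc5ac and log2 2.03, adjusted p = 0.0217 for Muc5b. The chemokine genes Ccl11 (log2 3.18, adjusted p = 0.0101) and Ccl17 (log2 3.21, adjusted p = 0.000533) and the resistin-like gene Retnla (log2 5.10, adjusted p = 5.71e-06) passed in the same fit. With all 12 arrays these measured 2.59 (adjusted p = 0.0608), 1.91 (0.159) and 3.17 (0.128). The interleukin genes Il4, Il5 and Il13 did not pass with either set of arrays, and Il13 measured log2 0.36 (adjusted p = 0.452). No member of the eosinophil list passed, with Epx at log2 1.10 (adjusted p = 0.0892) and Prg2 at 0.66 (0.256), and as a set the list was higher (camera, adjusted p = 0.0419, 0.484 with an estimated correlation). No inflammasome gene passed, with Il1b at log2 0.63 (adjusted p = 0.554) and Nlrp3 at 0.77 (0.344).

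Among the fixed gene lists, cell cycle genes were higher as a set in eosinophilic mice (camera, adjusted p = 7.58e-09, but 0.288 with an estimated correlation). Of 26 members 1 was higher and 25 were not past the threshold, against 17 higher adjusted over the list alone, for example Top2a (log2 1.79, adjusted p = 0.0648) and Nusap1 (log2 1.30, adjusted p = 0.0701). The alternatively activated macrophage list was higher (adjusted p = 1.02e-05, 0.484 with an estimated correlation), with 4 of 10 members past the threshold and 7 over the list alone. The type 2 list was higher (adjusted p = 5.2e-05, 0.0701 with an estimated correlation), with 1 of 19 members past and 5 over the list alone. The goblet cell list was also higher (adjusted p = 0.000145, 0.0701 with an estimated correlation), with 0 of 16 members past and 5 over the list alone. The neutrophil list was higher as a set (adjusted p = 0.00226, 0.484 with an estimated correlation), while none of its 19 members passed, with Il1r2 at log2 1.62 (adjusted p = 0.147).

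The tight junction list was lower in eosinophilic mice (camera, adjusted p = 1.85e-05, 0.484 with an estimated correlation). None of its 30 members passed over all genes, and 12 were lower over the list alone, among them Magi3 (log2 -1.82, adjusted p = 0.0547) and Mpp5 (log2 -1.84, adjusted p = 0.0588). Its median of -0.84 log2 lay at percentile 8.74 of random lists matched in expression, whose own median was -0.66. Without mouse 7 it lay at percentile 1.18 (median -0.56, matched lists -0.29). The blood endothelium list (adjusted p = 1.02e-05, 0.484 with an estimated correlation) had 1 of 14 members lower, 8 over the list alone, with Tek at log2 -2.69 (adjusted p = 0.0677). The alveolar type 1 list (adjusted p = 0.000165, 0.484 with an estimated correlation) had 1 of 9 lower, 7 over the list alone, with Rtkn2 at log2 -1.75 (adjusted p = 0.067). Mouse 7 carried much of the size of these falls: the median of the endothelial members was -1.99 log2 with all arrays and -1.02 without it, and that of the tight junction members -0.84 and -0.56. Matched random lists shrank as well, for endothelium from -1.44 to -0.43. The endothelial median lay at percentile 0.15 of them with all arrays and 0.06 without mouse 7. The mucin list (adjusted p = 0.0914) and the inflammasome list (0.314) did not pass. Of 46 lists 12 were higher and 10 lower by camera, none held with an estimated correlation, and 5 passed fry, which asks whether the members change at all rather than more than other genes. Without mouse 7, 3 lists held with an estimated correlation, goblet cell (adjusted p = 0.0246), type 2 (0.0268) and alternatively activated macrophage (0.0268).

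In total 99 of 19937 genes differed between eosinophilic and control mice (limma, adjusted p under 0.05), 15 higher and 84 lower, and all 99 by at least 2-fold. Without mouse 7 the count was 266 (90 higher, 176 lower), which held all 99 in the same direction, and 432 (294 higher, 138 lower) without mice 7, 9 and 23, a fit with 1 eosinophilic mouse (n = 1 and 3) and the spread of the other groups. The 3 values of one group lay wholly beyond those of the other in 27% of genes, where chance gives 10%. None of the other 9 splits of these 6 arrays gave a gene, although 10 splits allow no p under 0.1. The count depended on single arrays and on scaling: it was 1 without any one of the control mice or without mouse 9, 8264 without mouse 8, and 0 when only these 6 arrays were fitted. Of 19 genes named above as past the threshold, Pon1 alone stayed past it whichever array of the 2 groups was left out (highest adjusted p = 0.0488, without control 2). Centring each array on its median moved the median of all genes to -0.24 log2 and left 2 genes (0 higher, 2 lower), while quantile normalization gave 51 (31 higher, 20 lower).

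The comparison of mixed with control mice asked what weekly intranasal exposure at the low dose changed. The largest rise was in Clca1, with a mean of 11.76 log2 (SD 0.23, n = 3) against 4.41 (SD 0.14, n = 3) in controls. This was 163-fold (SE 0.94 log2, limma, adjusted p = 0.00829). The SE also carries the eosinophilic SD of 2.77 through the pooled spread. Without mouse 7 the adjusted p was 2.08e-08 at the same log2 change. Saa3 (log2 6.47, SE 0.54, adjusted p = 0.000221), Slc26a4 (log2 6.20, SE 0.91, adjusted p = 0.0137) and Rnase2a (log2 5.65, SE 0.96, adjusted p = 0.0242) came next. The neutrophil chemoattractant genes Cxcl2 (log2 5.63, adjusted p = 0.0133), Cxcl5 (log2 4.68, adjusted p = 0.000221), Cxcl1 (log2 3.33, adjusted p = 0.0268) and Cxcl3 (log2 3.26, adjusted p = 0.000991) all rose, as did Cxcl10, an interferon-induced chemokine gene (log2 5.17, adjusted p = 0.0187).

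Type 2 chemokine genes rose in mixed mice, with Ccl17 (log2 4.61, adjusted p = 0.027), Ccl8 (log2 4.76, adjusted p = 0.0385), the eosinophil attractant Ccl11 (log2 4.49, adjusted p = 0.00829) and Ccl22 (log2 3.56, adjusted p = 0.00837) past the threshold. Chil3 (log2 4.11, adjusted p = 0.0157) and Chil4 (log2 3.88, adjusted p = 0.00829) rose, and Retnla measured log2 5.22 (adjusted p = 0.0713, 5.37e-07 without mouse 7). Arg1 measured 2.65 (adjusted p = 0.116). Il13 (log2 0.68, adjusted p = 0.752) and Il33, an epithelial alarmin gene (log2 2.99, adjusted p = 0.239), did not pass with 12 arrays. Without mouse 7 Il33 did (adjusted p = 0.00036). No member of the eosinophil list passed, the furthest being the lipoxygenase gene Alox15 (log2 1.51, adjusted p = 0.46), and as a set they were higher (camera, adjusted p = 0.0132, 0.194 with an estimated correlation).

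Mucin and inflammasome genes were measured as study topics. Muc5ac rose in mixed mice (log2 2.67, SE 0.36, adjusted p = 0.00874), and the goblet cell trefoil gene Tff2 rose (log2 2.96, SE 0.39, adjusted p = 0.00829). Muc5b measured log2 2.92 (adjusted p = 0.135, 0.00036 without mouse 7) and the membrane mucin gene Muc4 1.62 (adjusted p = 0.135, 0.00378 without mouse 7). Of the inflammasome list, Il1b (log2 3.43, adjusted p = 0.0837), the inflammatory caspase gene Casp4 (log2 2.63, adjusted p = 0.126) and Il1a (log2 2.44, adjusted p = 0.221) passed only when mouse 7 was left out, at adjusted p = 0.0107, 0.00695 and 0.0247. Casp1 (log2 0.72, adjusted p = 0.549) and Nlrp3 (1.14, 0.749) did not pass in either fit. The camera test placed the mucin list higher (adjusted p = 0.00474, 0.194 with an estimated correlation), with 1 of 13 members higher and 3 over the list alone. It placed the inflammasome list higher (adjusted p = 0.00293, 0.134 with an estimated correlation), with 0 of 23 past and 3 over the list alone.

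In mixed mice no tight junction member passed over all 30, with the scaffold gene Magi3 at log2 -1.34 (adjusted p = 0.178) and the claudin gene Cldn4 at 1.81 (0.245). Nectin3 measured -1.15 (adjusted p = 0.151, 0.0287 without mouse 7), and the E-cadherin gene Cdh1 -0.16 (1). The tight junction list was lower by camera (adjusted p = 0.0398, 0.628 with an estimated correlation), with 1 member higher and 2 lower over the list alone. The adherens junction list was lower as well (adjusted p = 0.0444, 0.628 with an estimated correlation).

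Falls in mixed lung were led by Lrat, a retinol acyltransferase gene of stellate cells and fibroblasts (log2 -2.73, SE 0.41, adjusted p = 0.0152), and by the endothelial genes Myct1 (log2 -2.66, adjusted p = 0.00279) and Clec14a (log2 -2.17, adjusted p = 0.0163). The potassium channel gene Kcnj13 (log2 -2.39, adjusted p = 0.00539), the kinase gene Nuak1 (log2 -2.15, adjusted p = 0.026) and Hykk (log2 -2.10, adjusted p = 0.016) also fell. The club cell gene Cckar (log2 -2.06, adjusted p = 0.04) and the clock gene Per3 (log2 -1.63, adjusted p = 0.0211) were lower. The blood endothelium list was lower (camera, adjusted p = 0.000127, 0.529 with an estimated correlation) with 0 of 14 members past the threshold and 5 without mouse 7, when Kdr reached adjusted p = 0.00114 (log2 -2.15).

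Of the 46 lists 19 were higher and 5 lower in mixed mice by camera, 9 passed fry, and 5 of the higher lists also held with an estimated correlation. Without mouse 7 these 5 held and the alternatively activated macrophage list did too (0.0112, 0.0519 with all 12 arrays). The IL-17 and neutrophil chemoattractant list had 5 of 15 members higher, 8 over the list alone (camera, adjusted p = 1.32e-17, 0.0143 estimated). It included Il6 (log2 2.66, adjusted p = 0.0346), while Il17a measured log2 0.09 (adjusted p = 1). The acute phase list had 4 of 19 higher, 12 over the list alone (adjusted p = 2.41e-17, 0.0143 estimated), with Steap4 (log2 4.07, adjusted p = 0.00837), the antimicrobial lectin gene Reg3g (log2 4.18, adjusted p = 0.016) and Orm1 (log2 3.07, adjusted p = 0.00837). The neutrophil list had 1 of 19 higher, 11 over the list alone (adjusted p = 1.94e-19, 0.0158 estimated), with the decoy receptor gene Il1r2 (log2 3.40, adjusted p = 0.045), Ly6g (log2 3.18, adjusted p = 0.0512) and S100a9 (log2 2.57, adjusted p = 0.0513). The type 2 list (4 of 19 higher, 9 alone, adjusted p = 6.07e-14, 0.00219 estimated) and the goblet cell list (3 of 16, 7 alone, adjusted p = 2.36e-13, 0.00179 estimated) completed them. The interferon list had 3 of 21 higher, 15 over the list alone (adjusted p = 1.25e-26, 0.0519 with an estimated correlation), with Oasl1 (log2 2.80, adjusted p = 0.0216) and Mx1 (log2 1.99, adjusted p = 0.027).

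In total 94 genes differed between mixed and control mice (limma, adjusted p under 0.05), 65 higher and 29 lower, all by at least 2-fold. Without mouse 7, whose array enters only through the shared spread, the count was 596 (282 higher, 314 lower), and 1859 (716 higher, 1143 lower) without mice 7, 9 and 23. The groups lay wholly apart in 23% of genes, where chance gives 10%, and no other split of the 6 arrays gave a gene. Leaving out control 1, 2 or 3 left 6, 6 and 25 genes, leaving out mixed 15, 16 or 17 left 7, 21 and 19, centring each array left 23 (14 higher, 9 lower), and quantile normalization gave 86 (71 higher, 15 lower). Of 33 named genes past the threshold 4 stayed past it whichever array of the 2 groups was left out, namely Saa3 (highest adjusted p = 0.00373, without control 3), Cxcl5 (0.00346, without mixed 15), Cxcl3 (0.0153, without control 2) and Myct1 (0.0383, without control 1).

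The comparison of neutrophilic with control mice asked what the high intranasal dose changed. Clca1 rose most (log2 6.91, SE 0.94, adjusted p = 0.00718), followed by Saa3 (log2 6.12, SE 0.54, adjusted p = 0.000423) and Slc26a4 (log2 5.85, SE 0.91, adjusted p = 0.00977). The immunoglobulin light chain gene Igkv9-120 rose (log2 5.69, SE 0.91, adjusted p = 0.0114), as did Cxcl10 (log2 5.63, adjusted p = 0.00854) and Ccl3, a chemokine gene of activated myeloid cells (log2 5.15, adjusted p = 0.0123). Cxcl2 (log2 4.66, adjusted p = 0.0145), Cxcl5 (log2 4.54, adjusted p = 0.000254), Cxcl1 (log2 3.55, adjusted p = 0.0115) and Cxcl3 (log2 3.11, adjusted p = 0.000963) rose, and of the IL-17 cytokines Il17f did (log2 1.30, adjusted p = 0.0354) while Il17a measured log2 0.71 (adjusted p = 0.446).

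Neutrophil genes were higher after the high dose. S100a9 (log2 3.34, SE 0.51, adjusted p = 0.00936), S100a8 (log2 2.66, adjusted p = 0.0209), Il1r2 (log2 3.68, adjusted p = 0.0148), Ly6g (log2 3.08, adjusted p = 0.029), the collagenase gene Mmp8 (log2 2.70, adjusted p = 0.0424), the activating receptor gene Trem1 (log2 2.61, adjusted p = 0.0328) and Cd177 (log2 2.63, adjusted p = 0.0472) all rose. These were 7 of 19 list members, with 14 over the list alone (camera, adjusted p = 1.11e-13, 0.0538 with an estimated correlation). The IL-17 list had 6 of 15 members higher, 12 over the list alone (adjusted p = 3.19e-14, 0.0307 estimated, 0.0783 estimated without mouse 7).

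Type 2 chemokines rose in neutrophilic mice too, with Ccl8 (log2 5.09, adjusted p = 0.0146), Ccl17 (log2 4.23, adjusted p = 0.0209), Ccl11 (log2 4.16, adjusted p = 0.00755) and Ccl22 (log2 3.34, adjusted p = 0.00813), together with Il10 (log2 2.36, adjusted p = 0.0215) and the receptor gene Ccr8 (log2 2.09, adjusted p = 0.0424). The type 2 list held with preset and estimated correlation (6 of 19 higher, 6 alone, adjusted p = 2.02e-07 and 0.0217, but 0.0512 with an estimated correlation without mouse 7). Chil3 (log2 3.65, adjusted p = 0.0139), Chil4 (log2 2.32, adjusted p = 0.0367), the macrophage elastase gene Mmp12 (log2 3.25, adjusted p = 0.0424) and Arg1 (log2 2.76, adjusted p = 0.0496) rose, 4 of the 10 alternatively activated macrophage members (camera, adjusted p = 2.23e-09, 0.199 with an estimated correlation). No eosinophil gene passed, with Prg2 at log2 0.76 (adjusted p = 0.424) and Epx at 0.58 (0.407), while the set was higher (camera, adjusted p = 0.023, 0.231 with an estimated correlation). Il13 measured 0.38 (adjusted p = 0.672).

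Muc5ac rose (log2 2.62, SE 0.36, adjusted p = 0.00756) and Tff2 rose (log2 3.08, SE 0.39, adjusted p = 0.00437) in neutrophilic mice. Muc5b measured log2 2.73 (adjusted p = 0.0841, 0.000451 without mouse 7). The goblet cell list held with preset and estimated correlation (3 of 16 higher, 5 alone, adjusted p = 5.77e-09 and 0.00777, 0.0151 without mouse 7), and the mucin list passed with the preset correlation alone (adjusted p = 0.00971, 0.231 with an estimated correlation). Of the inflammasome list, the pyrin gene Mefv (log2 1.76, adjusted p = 0.0424) and Il1b (log2 3.28, adjusted p = 0.0498) rose. These were 2 of 23 members, 2 over the list alone (camera, adjusted p = 0.00971, 0.216 with an estimated correlation). Nlrp3 (log2 1.63, adjusted p = 0.187), Casp1 (0.77, 0.249) and Il18 (-0.57, 0.552) did not pass.

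Barrier genes that fell in neutrophilic mice were Nectin3 (log2 -1.85, SE 0.30, adjusted p = 0.0118), the polarity gene Mpp5 (log2 -2.03, SE 0.40, adjusted p = 0.0252) and Magi3 (log2 -1.76, adjusted p = 0.0346). Cldn4 measured log2 2.33 (adjusted p = 0.0535, 0.00622 without mouse 7), the alveolar claudin gene Cldn18 -1.33 (adjusted p = 0.537, 0.0286 without mouse 7) and Tjp1, which encodes zonula occludens protein 1, was 3.99-fold lower (adjusted p = 0.228, 0.00157 without mouse 7). The tight junction list had 2 of 30 members lower, with 1 higher and 5 lower over the list alone (camera, adjusted p = 0.0031, 0.547 with an estimated correlation). Its median of -0.37 log2 lay at percentile 22.4 of matched random lists. Cdh1 (log2 -0.22, adjusted p = 0.915) and Epcam (-0.41, 0.753) did not pass.

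Lrat (log2 -3.94, SE 0.41, adjusted p = 0.00108), Lurap1l (log2 -3.09, adjusted p = 0.0187), Kcnj13 (log2 -3.04, adjusted p = 0.000675) and Pon1 (log2 -2.88, adjusted p = 0.000963) fell most in neutrophilic mice, with Nbeal1 (log2 -2.86, adjusted p = 0.00443) and the endothelial lectin gene Clec1a (log2 -2.80, adjusted p = 0.0267). Akap5 (log2 -2.72, adjusted p = 0.0178) and Rtkn2 (log2 -2.20, adjusted p = 0.0191) of alveolar type 1 cells, Cckar of club cells (log2 -2.73, adjusted p = 0.00813), Sntn of ciliated cells (log2 -1.74, adjusted p = 0.0114) and the clock gene Per3 (log2 -1.80, adjusted p = 0.00897) fell. The alveolar type 1 list was lower (camera, adjusted p = 0.00332, 0.534 with an estimated correlation), as was the blood endothelium list (0.00024, 0.534 with an estimated correlation), and 5 of its 14 members were lower over the list alone.

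By camera 20 of the 46 lists were higher and 5 lower in neutrophilic mice, 3 held with an estimated correlation (1 without mouse 7, the goblet cell list), and 11 passed fry. Among acute-phase and interferon genes, Steap4 (log2 3.70, adjusted p = 0.00813), Reg3g (log2 3.31, adjusted p = 0.0225), Orm1 (log2 2.70, adjusted p = 0.00907), Oasl1 (log2 3.24, adjusted p = 0.00813) and Mx1 (log2 1.67, adjusted p = 0.0315) rose. The interferon list (camera, adjusted p = 3.19e-14, 0.199 with an estimated correlation) had 4 of 21 members higher, and the acute phase list (2.47e-10, 0.0538 with an estimated correlation) 4 of 19. Il2ra of activated T cells (log2 3.27, adjusted p = 0.0201), Cd14 (log2 4.24, adjusted p = 0.0215) and Ccl2 (log2 3.83, adjusted p = 0.0143) of monocytes, and the immunoglobulin genes Ighm (log2 3.25, adjusted p = 0.0267) and Jchain (log2 3.90, adjusted p = 0.0325) also rose.

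In total 421 genes differed between neutrophilic and control mice (limma, adjusted p under 0.05), 132 higher and 289 lower, all by at least 2-fold. Without mouse 7 the count was 1889 (447 higher, 1442 lower), and 3188 (1149 higher, 2039 lower) without mice 7, 9 and 23 (n = 2 and 3). The groups lay wholly apart in 33% of genes, where chance gives 10%, and no other split of the 6 arrays gave a gene. Leaving out control 1, 2 or 3 left 17, 21 and 157 genes, and leaving out neutrophilic 24 or 25 left 84 and 43. The balance of directions turned without neutrophilic 23 (365 genes, 215 higher, 150 lower) and with quantile normalization (248, 135 higher, 113 lower), and centring each array gave 168 (46 higher, 122 lower). Of 57 named genes past the threshold 8 stayed past it whichever array of the 2 groups was left out: Saa3, Cxcl5, Cxcl3, Tff2, Lrat, Kcnj13, Pon1 and Nbeal1 (highest adjusted p = 0.0443, without control 1).

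**Figure D2:**
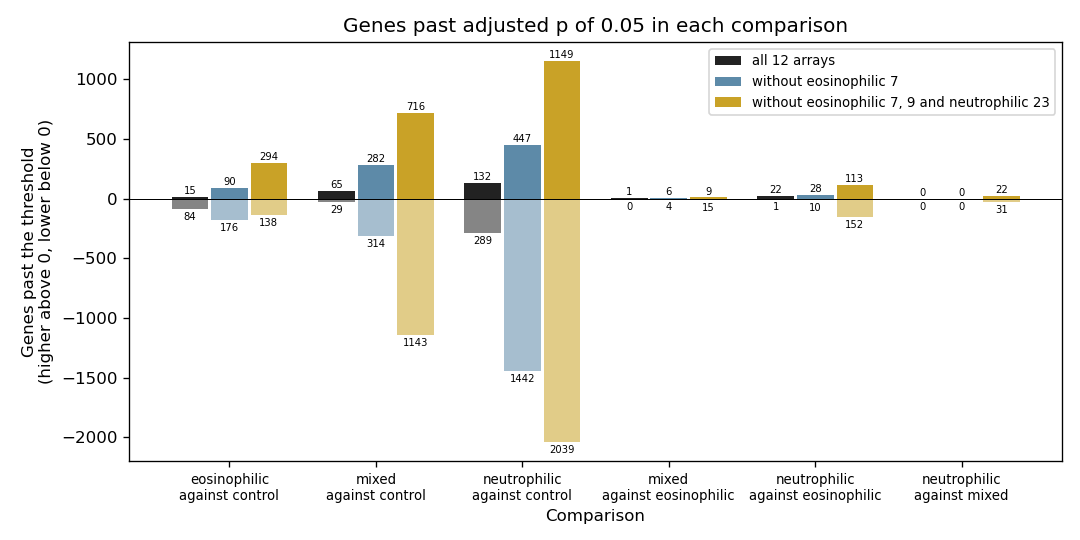
Genes past the threshold in each comparison. Leaving out the array of eosinophilic mouse 7 raised the neutrophilic count from 421 to 1889.

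**Figure D3:**
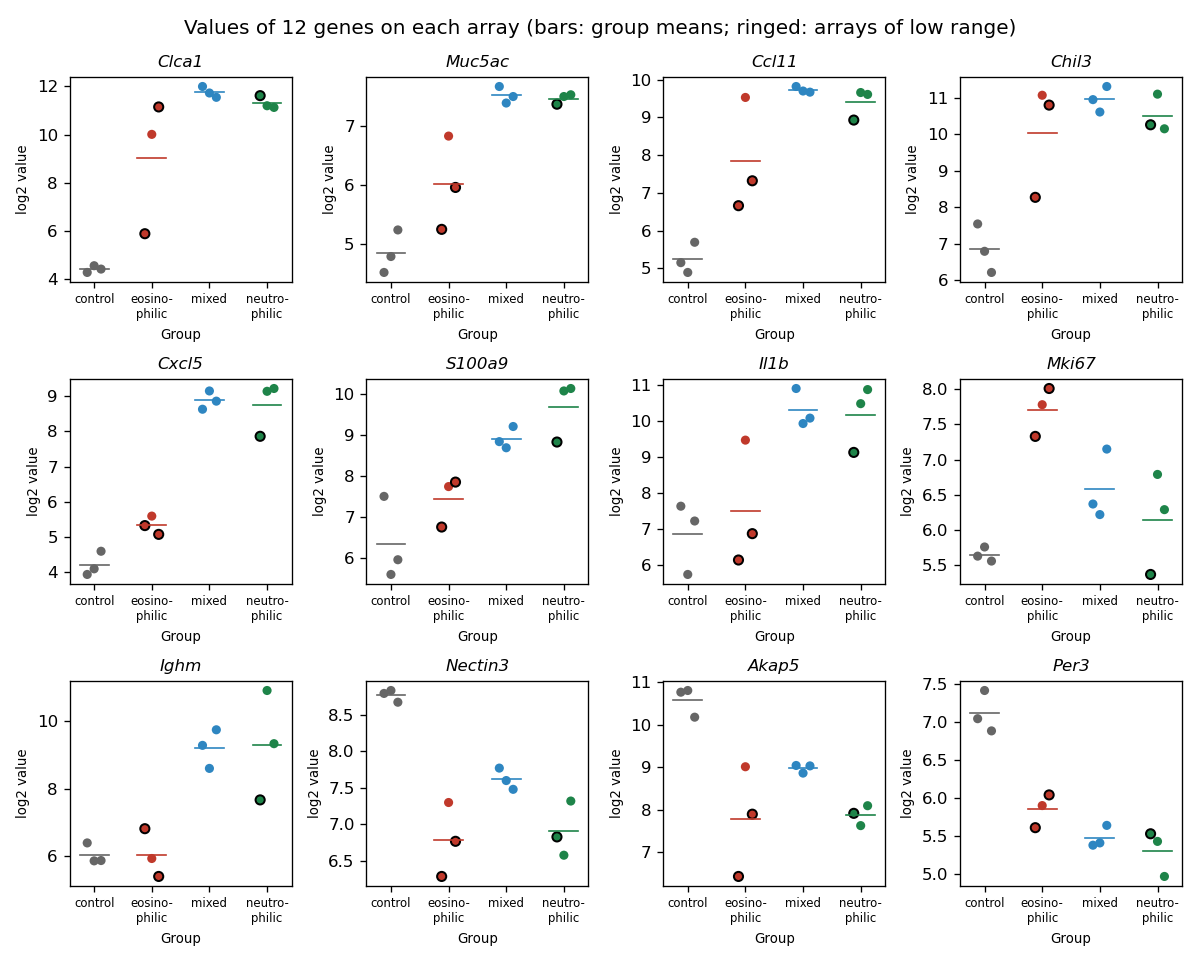
Values of 12 genes on each array. Clca1 had a mean of 4.41 log2 in controls, 9.02 in eosinophilic, 11.76 in mixed and 11.32 in neutrophilic mice.

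The phenotypes were then compared with each other. Between mixed and eosinophilic mice, which received the same extract dose by different routes, schedules and with or without alum, 1 gene passed. This was the neutrophil chemoattractant gene Cxcl5, with a mean of 8.88 log2 (SD 0.26) in mixed and 5.33 (SD 0.26) in eosinophilic mice (log2 3.56, SE 0.37, adjusted p = 0.00805, n = 3 and 3). Cxcl1 measured log2 3.27 (adjusted p = 0.155, 0.0187 without mouse 7) and Ighm 3.15 (adjusted p = 0.193). The mitotic genes Top2a (log2 -1.45, adjusted p = 0.295) and Nusap1 (-1.21, 0.295) did not pass. Cldn4 measured 2.59 (0.227) and Arg1 -1.25 (0.311).

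As a set, cell cycle genes were lower in mixed than in eosinophilic mice (camera, adjusted p = 1.18e-09, 0.535 with an estimated correlation), with 8 of 26 members lower over the list alone and a median of -0.85 log2. The IL-17 list was higher (adjusted p = 0.000282, 0.535 with an estimated correlation), with 7 of 15 members higher over the list alone. The neutrophil list was higher too (adjusted p = 0.00153, 0.539 with an estimated correlation), with 7 of 19 over the list alone. The tight junction list was higher in mixed mice (adjusted p = 0.000411, 0.539 with an estimated correlation), with its median at 0.62 log2 and 0.27 without mouse 7. Matched random lists rose nearly as much (0.52, percentile 82.5), and without mice 7, 9 and 23, with 1 eosinophilic mouse left, the list did not pass (median 0.06, adjusted p = 0.119). The goblet cell (0.315), mucin (0.723) and inflammasome (0.345) lists did not differ by this test. None of the 22 lists past the threshold held with an estimated correlation, and none passed fry. The limma count of 1 became 10 without mouse 7, 5979 without mouse 8, 6 without mixed 15 and 0 without mouse 9, mixed 16 or mixed 17.

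Between neutrophilic and eosinophilic mice 23 genes passed (limma, adjusted p under 0.05), 22 higher and 1 lower. Igkv9-120 was higher (log2 6.87, SE 0.91, adjusted p = 0.013), as were Cxcl1 (log2 3.49, SE 0.58, adjusted p = 0.0459) and Cxcl5 (log2 3.41, SE 0.37, adjusted p = 0.0116). The small RNA genes Vaultrc5 (log2 3.95, adjusted p = 0.0116) and Scarna13 (log2 3.27, adjusted p = 0.0245) and Sprr1a, a gene of the squamous epithelial envelope (log2 2.75, adjusted p = 0.0116), were higher. Anln, which encodes a protein of the dividing cell cortex, was lower (log2 -1.69, adjusted p = 0.0466). Cldn4 measured log2 3.11 (adjusted p = 0.072), S100a9 2.24 (0.194), Mki67 -1.56 (0.244) and Arg1 -1.14 (0.519). Without mouse 7 Arg1 was lower in neutrophilic mice (log2 -2.11, adjusted p = 0.0338).

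The IL-17 list was higher in neutrophilic than in eosinophilic mice (2 of 15 members, 6 alone, camera, adjusted p = 7.79e-09, 0.229 with an estimated correlation). The neutrophil list was higher (adjusted p = 9.3e-06, 0.316 with an estimated correlation) and the plasma cell and immunoglobulin list was higher (4.56e-05, 0.316 with an estimated correlation), with 7 of 11 members over the list alone. Cell cycle genes were lower (adjusted p = 7.79e-09, 0.311 with an estimated correlation), 5 of 26 over the list alone. The goblet cell (0.167), mucin (0.463) and inflammasome (0.142) lists did not pass. Of 19 lists past the threshold none held with an estimated correlation, and 2 passed fry. Without mouse 7, 5 of these lists turned direction, and so did 2 of those past the threshold for mixed against eosinophilic mice. The blood endothelium list alone passed after turning, from higher with all 12 arrays (camera, adjusted p = 0.0163, 0.616 with an estimated correlation) to lower without mouse 7 (0.0111). That call did not hold with an estimated correlation either, as no list of this comparison did without mouse 7.

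Another split of these 6 arrays, with eosinophilic 7 and 9 and neutrophilic 23 on one side, gave 6704 genes against the real 23, and those are the 3 arrays of low range. The real groups lay wholly apart in 8.21% of genes, below the 10% of chance, and mixed and eosinophilic mice did in 13%. The count was 38 without mouse 7 (28 higher, 10 lower), 2777 without mouse 8, 4 without mouse 9, 44 without neutrophilic 23 and 0 without neutrophilic 24 or 25. Centring each array moved the median of all genes to 0.13 log2 here and to 0.19 for mixed against eosinophilic mice, with 14 and 1 genes past the threshold.

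Between neutrophilic and mixed mice, which shared route and schedule and differed in dose, no gene passed. An unadjusted p under 0.05 (limma) was found for 618 of 19937 genes, a share below the 0.05 that chance alone would give. Mouse 7 is in neither group and enters only through the pooled spread. Without it 1459 genes had such a p, a share above 0.05. The groups lay wholly apart in 14% of genes, where chance gives 10%. Clca1 measured log2 -0.44 (SE 0.94), Muc5ac -0.05 (SE 0.36), Il1b -0.14 (SE 0.77), Cxcl5 -0.14 (SE 0.37), Ccl11 -0.33 (SE 0.57) and Nectin3 -0.70 (SE 0.30), each with n = 3 and 3. Chil4 measured -1.56 (SE 0.50) and S100a9 0.77 (SE 0.51). The ciliated cell list was lower at the high dose (camera, adjusted p = 0.000166, 0.976 with an estimated correlation), with a median of -0.33 log2 and Sntn at -1.08. The tight junction (0.111), mucin (0.846) and inflammasome (0.846) lists did not pass. The direction of lists depended on single arrays. By camera 5 lists were higher and 5 lower without mixed 17, and 0 higher and 7 lower without mouse 7. Among single arrays neutrophilic 23 moved them most. With all arrays 0 lists were higher and 2 lower, without that array 12 higher and 2 lower, and 13 higher and 6 lower without mice 7, 9 and 23, where the fit gave 53 genes (22 higher, 31 lower).

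**Figure D4:**
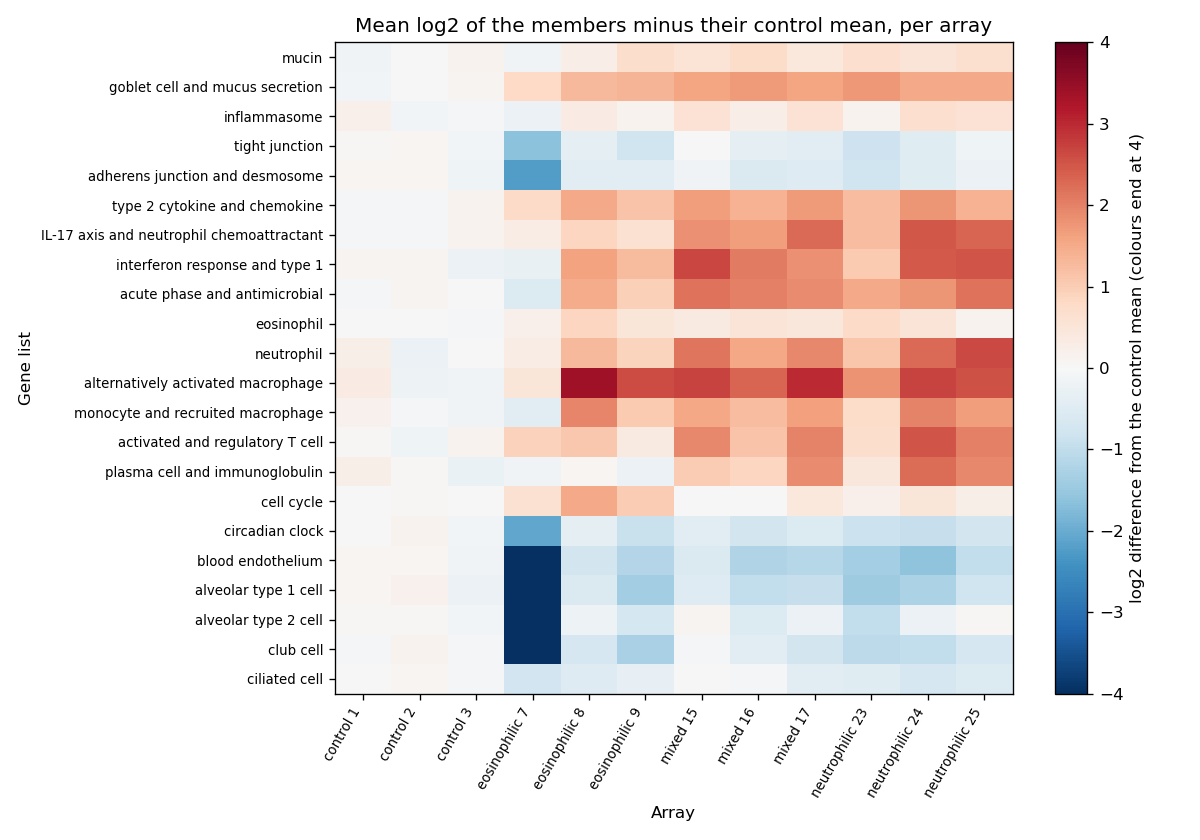
Mean of the members of each list on each array, relative to controls. On the array of eosinophilic mouse 7 the alveolar type 2 list lay at -4.90 log2 and the blood endothelium list at -4.17.

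Over all 4 groups, 176 genes differed by the limma F test (adjusted p under 0.05), and 918 did without mouse 7. Single arrays moved this count from 8 without control 2 to 5237 without eosinophilic 8. Calls against control were shared between phenotypes. Mixed and neutrophilic mice shared 85 genes against control, 58 higher and 27 lower (0.43 and 0.42 by n1 x n2 / N), and none in opposite directions. Genes shared as higher included Clca1, Saa3, Slc26a4, Muc5ac, Tff2, Cxcl5 and Ccl11, and those shared as lower Lrat, Kcnj13 and Per3. Eosinophilic and neutrophilic mice shared 60 (11 higher, 49 lower, against 0.0993 and 1.22), among them Saa3, Chil3, Chil4, Nectin3, Akap5, Sntn and Pon1. Eosinophilic and mixed mice shared 20 (7 higher, 13 lower, against 0.0489 and 0.122), among them Saa3, Rnase2a, Ccl8, Chil3, Chil4 and Cxcl3. Log2 changes of all genes correlated at 0.816 for mixed with neutrophilic, 0.679 for eosinophilic with neutrophilic and 0.502 for eosinophilic with mixed, against 0.354, 0.214 and 0.249 in simulated groups without change that shared the control arrays. Covariances exceeded the simulated ones by 0.263, 0.366 and 0.194. With 3 controls they could not be split into separate sets, so part of the excess may come from the controls that all comparisons share. The simulated noise was independent between genes, so it lacked the general fall of abundant genes on arrays of low range. Such arrays lay in both the eosinophilic and neutrophilic groups, the pair with the largest excess. Some of the excess may come from them too. Without mouse 7 the excesses were 0.271, 0.281 and 0.185, in the same order. Shared counts were as unstable as the calls. From 85, 60 and 20 they became 530, 229 and 164 without mouse 7, 5, 1 and 0 without control 1 or without control 2, and 22, 2 and 1 with each array centred.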

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

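The tests on the array of eosinophilic mouse 7, on plasma cell genes and on resident cell and junction lists were chosen after values of these arrays and of some members had been seen, as was the place of the low-range arrays in the regroupings, while the regroupings themselves were set before their results were known.

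Differences between phenotypes were picked out because 2 groups exposed to the same allergen differed under one test. Between mixed and eosinophilic mice 1 gene differed, Cxcl5 (log2 3.56). Between neutrophilic and eosinophilic mice 23 genes differed, with Igkv9-120 (log2 6.87), Vaultrc5 (3.95), Cxcl1 (3.49), Cxcl5 (3.41), Scarna13 (3.27) and Sprr1a (2.75) higher and Anln (-1.69) lower. Probe sets that could not be assigned to a single gene were picked out because they lay outside the gene-level tests. Of these, 7 passed the threshold in mixed and 37 in neutrophilic against control mice, 18 in neutrophilic against eosinophilic mice (15 higher, 3 lower), and 0 in the other comparisons.

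Regrouping of the arrays gave a first check on the counts. Each pair of groups has 10 splits, too few for a share under 0.05. The real grouping was the only 1 of 10 to reach its own count for eosinophilic (99 genes, highest other 0), mixed (94, highest other 0) and neutrophilic (421, highest other 0) against control, and for mixed against eosinophilic (1 gene, highest other 0). For neutrophilic against eosinophilic mice 2 splits reached the real 23, and the other one gave 6704 with eosinophilic 7 and 9 and neutrophilic 23 together, which points to a structure of the samples. For neutrophilic against mixed mice all 10 splits reached the real count of 0, and the highest other gave 4. For the 4 groups, 4 of 100 splits, the real one included, reached 176 genes, fewer than the 5 set as the limit, and the highest other gave 3762. Without mouse 7, 5 of 100 reached 918 (highest other 3435), which meets that limit, so the grouping stands at its edge. The 3 other splits that reached 176 were the only 3 of 99 with eosinophilic 7 and 9 and neutrophilic 23 in one group. Without mouse 7 the 4 that reached 918 had eosinophilic 9 and neutrophilic 23 in one group, as had 19 of 99.

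Mouse 7 may have given a poor array. The slope of its gene values on the control mean was 0.169, below the 0.5 set for low range. A slope follows from the SD and the correlation that had already singled out this array, and another tissue could lower it too. The slope therefore cannot decide whether low range is the cause. Another tissue or an exchanged sample was expected to leave stable abundant transcripts in place, and these lay -3.38 log2 from their level on the other 11 arrays. A low range lowers abundant transcripts whatever the tissue, so this test cannot decide, and another tissue or an exchanged sample stays open. An effect of the sensitisation was expected on the other eosinophilic arrays too, and the lower of their slopes was 0.662, which speaks against it as the whole cause. What made the range low was not tested.

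Plasma cell and immunoglobulin genes were higher in mixed and in neutrophilic than in eosinophilic mice by camera (adjusted p = 0.00351 and 4.56e-05), and neither call held with an estimated correlation (0.539 and 0.316). Without the 3 arrays of low range the difference was 0.859 log2, but 1 eosinophilic mouse was left, so low range of the eosinophilic arrays stays open as a cause. Lymphoid tissue taken with the lung would raise B cell and T cell genes as well. Their shifts were 0.699 and 0.308 log2 against the same single mouse, and the smaller was 0.359 of the plasma cell shift, so lymphoid tissue and plasma cells in the lung itself stay open too.

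Alveolar type 1, blood endothelium and tight junction lists were lower by camera in each HDM group than in controls. None of these calls held with an estimated correlation (adjusted p = 0.484 for each list in eosinophilic mice, and in mixed and neutrophilic mice 0.529 and 0.534 for alveolar type 1 cells and endothelium and 0.628 and 0.547 for tight junctions). The alveolar type 2 list did not pass in mixed (adjusted p = 0.369) or neutrophilic mice (0.36), nor the adherens junction list in neutrophilic mice (0.0849). Low range of some arrays might lower abundant genes in general. Random lists matched in expression were therefore set beside each list without the 3 such arrays, of which none is in the comparison of mixed with control mice, so leaving them out tests only the neutrophilic side. For alveolar type 1 cells the median lay at percentile 0.48 in mixed and 0.2 in neutrophilic mice, and for endothelium at 0.02 and 0. This speaks against low range as the whole cause of these falls. Genes of the random lists were drawn independently, while members of these lists moved together (estimated correlation 0.888 and 0.913). The percentiles may therefore overstate how unusual the falls are. For tight junctions the median lay at 2.98 and 7.11, the latter above the limit of 5, so low range stays open there. Dilution by infiltrating cells would lower all resident cell types alike only if their lists respond alike on these arrays, which was not tested. Medians ranged over 0.861 log2 and were all negative. They were -0.958 for endothelium, -0.881 for alveolar type 1, -0.712 for club cells and -0.418 for fibroblasts. Ciliated cells lay at -0.354 and alveolar type 2 cells at -0.0969. A pooled set of 82 genes of resident lists fell too, without the same 3 arrays. Its median was -0.444 log2 in mixed and -0.474 in neutrophilic mice, against -0.082 and -0.128 for matched random lists. A fall across resident lists would follow from dilution as well. The unequal medians therefore cannot decide, and dilution remains open for all these lists, as the whole cause or a part.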

How the results depend on the processing

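Counts of genes depended strongly on which arrays and which scaling entered the fit, while directions of the named genes did not. No named gene turned direction in any setting. Every gene past the threshold had all values of one group beyond those of the other, so leaving out arrays could not turn it. The balance of called genes did turn. For neutrophilic against control it went from 132 higher and 289 lower to 215 and 150 without neutrophilic 23. For eosinophilic against control it went from 15 and 84 to 31 and 20 with quantile normalization. In the order eosinophilic, mixed and neutrophilic against control, then mixed against eosinophilic, neutrophilic against eosinophilic and neutrophilic against mixed, the planned fit gave 99, 94, 421, 1, 23 and 0 genes, and 176 by the F test. Of 46 lists 22, 24, 25, 22, 19 and 2 passed camera. Shared calls were 20 for eosinophilic and mixed, 60 for eosinophilic and neutrophilic and 85 for mixed and neutrophilic mice. The cause of the moves below was not tested. No paired analysis was possible because the groups share no replicate numbers.

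Among planned settings, keeping genes with log2 of 5 or more gave 237 for eosinophilic against control, 8 and 11 lists for mixed and neutrophilic against eosinophilic, and 42 and 138 shared calls for eosinophilic with mixed and with neutrophilic. Keeping genes above the array median gave 244 for eosinophilic against control. Centring each array gave 2, 23 and 168 genes against control, 14 for neutrophilic against eosinophilic, 25 by the F test and 1, 2 and 22 shared calls. Quantile normalization gave 51 for eosinophilic and 248 for neutrophilic against control, 13 for neutrophilic against eosinophilic, and 1 list for neutrophilic against mixed. Trend and robust settings of eBayes gave 285, 240 and 694 against control, 7 for mixed against eosinophilic and 499 by the F test. Array weights, whose estimation did not converge, gave 15405, 3523, 5817, 12335, 11837 and 329, and 16709 by the F test. Fitting only the groups compared gave 0, 1689 and 2124 against control, and 0 for each comparison with eosinophilic mice. Testing all probe sets gave 1, 49 and 249 against control, 40 for neutrophilic against eosinophilic and 89 by the F test. With an estimated correlation 0, 5, 3, 0, 0 and 0 lists held, and fry passed 5, 9, 11, 0, 2 and 0.

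Leaving out mouse 7 gave 266, 596, 1889, 10 and 38 genes for the first 5 comparisons and 918 by the F test. It gave 7 lists for neutrophilic against mixed, and 164, 229 and 530 shared calls. The counts of 266, 10, 38 and 918 and the shared calls also belong to the planned leaving out of each array in turn. The other fits without mouse 7 were added after the arrays had been seen. So were those without mice 7, 9 and 23 and those with the SD as a covariate. Leaving out mice 7, 9 and 23, which left 1 eosinophilic and 2 neutrophilic mice and took the spread of the eosinophilic arm from the other groups, gave 432, 1859, 3188, 24, 265 and 53, with 2523 by the F test and 19 lists for neutrophilic against mixed. The SD of each array as a covariate gave 338, 1046 and 2173 against control, 110 for neutrophilic against eosinophilic, 5 for neutrophilic against mixed and 1391 by the F test. With mouse 7 also left out these were 751, 1759, 2906, 44, 394 and 12, and 2344. The list values that follow are from camera with the preset correlation. With an estimated correlation and without mouse 7, no list held in neutrophilic against eosinophilic mice (camera, adjusted p = 0.794 for blood endothelium). The blood endothelium list turned from higher to lower in neutrophilic against eosinophilic mice without mouse 7 (adjusted p = 0.0111) and without mice 7, 9 and 23 (0.00158). In mixed against eosinophilic mice it turned likewise, from higher (0.00351) to lower without mice 7, 9 and 23 (0.0437), and to lower short of the threshold without mouse 7 (0.752).

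Leaving out in turn each array of the groups compared moved counts over 1 to 8264 for eosinophilic, 6 to 25 for mixed and 17 to 365 for neutrophilic against control, 0 to 5979 for mixed against eosinophilic, 0 to 2777 for neutrophilic against eosinophilic and 8 to 5237 by the F test. Leaving out any of the 12 arrays, shared calls ranged over 0 to 164, 1 to 766 and 5 to 530. Lists ranged over 13 to 24 for eosinophilic against control and 1 to 14 for neutrophilic against mixed. Adjusted p of the blood endothelium list ranged over 0.000507 to 0.0778 in neutrophilic and 0.000123 to 0.752 in mixed against eosinophilic mice.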

Other observations

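The choice to single out fits without mouse 7 and to compare resident cell lists was made after the arrays had been seen. Genes and lists outside the study topics were looked at as well, and the clock and cardiac muscle lists did not hold with an estimated correlation. The clock gene Per3 fell in mixed (log2 -1.63, adjusted p = 0.0211) and neutrophilic mice (log2 -1.80, adjusted p = 0.00897) and measured log2 -1.26 (adjusted p = 0.0586) in eosinophilic mice. Its list was lower in all comparisons with control by camera (adjusted p = 0.00305, 0.0272 and 0.00684 for eosinophilic, mixed and neutrophilic mice, and 0.484, 0.529 and 0.494 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose in mixed (log2 5.11, adjusted p = 0.0352) and neutrophilic mice (log2 4.56, adjusted p = 0.0292). Cardiac muscle genes, which atrial tissue or pulmonary veins bring into a lung sample, were lower as a set in neutrophilic than in mixed mice (camera, adjusted p = 0.00112, 0.976 with an estimated correlation), with a median of -0.68 log2. Much of this came from mixed 16, whose list score was 1.13 log2 against -0.18 and 0.35 in mixed 15 and 17.

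The level of Cxcl5 may follow the intranasal schedule more than the dose. It was 3.56 log2 higher in mixed and 3.41 higher in neutrophilic than in eosinophilic mice, and it differed by -0.14 (adjusted p = 1) between the 2 intranasal doses. Without mouse 7 the adjusted p for mixed against eosinophilic mice was 0.00418, and without eosinophilic 9, mixed 16 or mixed 17 no gene passed. A dose effect on other members stays open, since the IL-17 and neutrophil chemoattractant list did not differ between the doses with all arrays (camera, adjusted p = 0.23) but was higher at the high dose without mice 7, 9 and 23 (median 0.52 log2, adjusted p = 0.000124). The time from the last exposure to sampling is not given in the sources used here, so schedule, route and sampling time cannot be separated in these data. A design that crosses route, alum and dose at a fixed sampling time, with Cxcl5 and Cxcl1 measured by PCR and neutrophils counted in lavage fluid, would separate these factors.

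Cell cycle genes were highest in eosinophilic mice, and this may reflect the challenges on days 26 to 28 rather than the phenotype. The list was lower in mixed than in eosinophilic mice at adjusted p = 5.45e-25 without mouse 7, but at 0.102 in the same fit with an estimated correlation. Staining for the Mki67 protein with cell type markers, at a fixed time after the last challenge in every model, would test this.

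Muc5ac and Clca1 rose in the intranasal models without a change in Il13 past the threshold (log2 0.68 and 0.38), so the cytokine transcript could have peaked earlier or in few cells. In eosinophilic mice Muc5ac reached adjusted p = 0.031 only without mouse 7. Protein levels of IL-13 in lavage fluid over the days after exposure would test it.

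Nectin3 fell in eosinophilic and neutrophilic mice, as did Akap5 of alveolar type 1 cells and Sntn of ciliated cells, so alveolar and airway epithelium both stay open as the site. Medians of the resident cell lists ranged over 0.861 log2 between cell types, so loss of one type and lower expression within it remain to be told apart. Sorted alveolar and airway epithelial cells, or tissue sections stained for nectin-3, would place it. A repeat of the array for mouse 7 from the stored RNA would show whether the low range arose in the array or the sample.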
